A study of Mus musculus with 6 samples.

How the data were processed

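RNA sequencing measured the transcriptomes of mouse bone marrow-derived macrophages, which are cells grown from marrow with the growth factor M-CSF. Marrow came from Cd28 knockout (Cd28 KO) and wild-type (WT, C57BL/6J) mice aged 6 to 10 weeks. Per the labels' protocols, cells were cultured for 7 days in medium with 10% serum and human M-CSF at 25 ng/ml, added every 2 days, with no further treatment. Each group had 3 libraries, grouped by their titles. The titles number the samples within each group, and no label used here says whether each number was a separate animal, a litter or a day, so p-values measure the spread between these samples. The sex of the mice is not given in the sources used here.

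The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with 1 value per gene and library. Per the submitters' processing notes, Bowtie and RSEM were used with genome build GRCm38. Their versions are not given in the sources used here. RSEM shares reads between genes with similar sequence by estimation, so values of near-identical copies are uncertain. A file listed only genes above 0, with 0.01 as its lowest value. A gene missing from a library's file was counted as 0 there. Gene identifiers were Entrez numbers, and 14551 of the 14574 listed in any library matched NCBI RefSeq for GRCm38, from which symbols and coordinates were taken, while 23 did not match. Protein-coding genes made up 99.65% of those listed.

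FPKM does not carry the number of reads, and the labels give no depth. Low values were examined for steps of whole fragments in 1068 genes with a single transcript. A search over depths placed the best fit at 9100000 to 9500000 fragments per library, where 58.1% to 68.7% of 96 to 129 low values lay within 0.15 of a whole number, against 30% by chance. The search chose the best of many depths, RSEM does not give whole reads, and the result was not used for a count test. The best fits of the 6 libraries lay close together. The search skipped depths with too few usable values by the same rule in each library, so equal depth is not shown. No 2 libraries shared more than 0.46% of their values of at least 1 FPKM, so no library was a copy of another.

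Differential expression was tested with limma 3.58.1 in R 4.3.3 (linear fit, empirical Bayes with trend) on log2(FPKM + 1), without a block. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 10172. Log2 fold changes, and counts of genes changed at least 2-fold, are on the log2(FPKM + 1) scale, which understates the change of low genes. Other folds are ratios of group means of FPKM. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The level of Cd28 was compared by an exact two-sided permutation test. A set of 40 gene lists was fixed before the data were examined, and 33 lists with at least 3 tested members went through limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fisher's exact test compared the share of called genes within 10 Mb of Cd28 with that of other tested genes. Other tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

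Whether the replicate numbers pair the libraries was checked from the deviations of each library from its group mean. These correlated across genes at 0.752 for replicates 1, 0.505 for replicates 2 and 0.783 for replicates 3. All 3 exceeded 0.1, so the numbers were taken to pair the samples, on the data and not on any label. The fit with the replicate number as a block is therefore given beside results whose call or count it changes. Not every library correlated best with its own number. Cd28 KO replicate 2 correlated at 0.535 with WT replicate 1, and WT replicate 2 at 0.66 with Cd28 KO replicate 1. The cut-off of 0.1 could not test the pairing of replicates 1 and 2. Deviations cancel within a group, and replicate 3 stood apart in both groups, which pushes all correlations among replicates 1 and 2 upward. The pairing of replicates 1 and 2 is therefore assumed, and only that of the replicate 3 libraries shows in the data.

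The genes named were fixed by rule before the data were examined. They are Cd28, the 10 highest and 10 lowest called genes whose groups do not overlap, filled up to 5 per direction by smallest p, up to 4 members of each list past the test and up to 2 of every other list. The genes called with the replicate block, the Y-linked genes and the examples from replicate 3 were chosen after their values were seen.

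The fits were tested on simulated data for Cd28 KO against WT over 10172 genes, with replicate effects as large as in these libraries and 50 changed genes per size. Without a block, 4% of genes changed 1.5-fold were recovered, 48% at 2-fold, 80% at 4-fold and 94% at 8-fold, with 0 unchanged genes called. With the replicate block the shares were 22%, 70%, 88% and 100%, with 1 unchanged gene called. The simulated noise was independent between genes and took its spread from the fit with the block, so that model held by construction. The counts of unchanged genes called therefore do not give the rate of false calls in these libraries.

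Alternatives chosen before the data were examined were a pseudocount of 0.1 FPKM, no filter, a minimum mean of 5 FPKM, scaling to a fixed sum (TPM scale), median centring, quantile normalization, robust empirical Bayes, array weights, the replicate block, leaving out each library in turn, and windows of 5 and 20 Mb. Alternatives added after seeing the data were a batch term for replicate 3, replicates 1 and 2 alone, leaving out genes of chromosome 1, combinations with the block, and an estimated correlation for the list tests of each alternative.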

Results

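Macrophages grown from the marrow of Cd28 KO and of WT mice were compared by RNA sequencing, with 3 libraries per group, to ask how gene expression differs between macrophages of these genotypes. Cd28 is a receptor best known as a costimulatory molecule of T cells. Each library listed between 12768 and 13327 genes, with 14574 listed in any library and 11835 in all 6. FPKM summed to 510937 to 576313 per library, and the 10 most abundant genes took 13.2% to 15.2% of each sum. The number of reads behind the values is not given in the sources used here.

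Cd28 (Entrez 12487, chromosome 1, 60746388 to 60773359, GRCm38) was lower in the Cd28 KO libraries but still listed in all of them. The 3 Cd28 KO libraries held 25.7, 24.2 and 26.9 FPKM, and the WT libraries 38.2, 30.1 and 51.1 FPKM. The means were 25.6 ± 1.38 FPKM in Cd28 KO and 39.8 ± 10.6 in WT (SD, n = 3 each), so that Cd28 KO stood at 64.3% of WT. Every Cd28 KO value lay below every WT value, at an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Cd28 was not called by limma in either fit. Its log2 fold change was -0.59 ± 0.19 (SE), with a limma adjusted p of 0.9995 without a block and 0.18 with the replicate block. The difference was -14.2 FPKM with all libraries and -8.56 FPKM without WT replicate 3. Gene-level values do not show which exons were read, and the targeted part of the gene is not given in the sources used here.

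The other genes of the same receptor family were near the lower end of the files. Ctla4 was listed in 1 library, at 0.06 FPKM, Pdcd1 in 1 library at 0.06 FPKM, and Icos and Btla did not exceed 0.25 FPKM in any library.

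The replicate 3 libraries of both genotypes stood apart from the other 4. Principal component 1 held 73.8% of the variance and placed both replicate 3 libraries, at 34.8 and 36.1, away from the rest, at -18.2 to -17.4. Among replicates 1 and 2 alone, examined after seeing the data, component 1 held 54.6% of the variance and separated the genotypes, with Cd28 KO at -10.4 and -10.3 and WT at 6.57 and 14.1. Y-linked genes were listed in replicate 3 of both groups and in no other library: Eif2s3y at 39.1 FPKM in Cd28 KO and 31.8 in WT, Ddx3y at 10.6 and 14.4, Kdm5d at 2.73 and 3.98, and Uty at 2.08 and 1.97. Each genotype had 1 such library, so the difference between replicates is balanced across the groups but widens the spread within each.

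**Figure D1:**
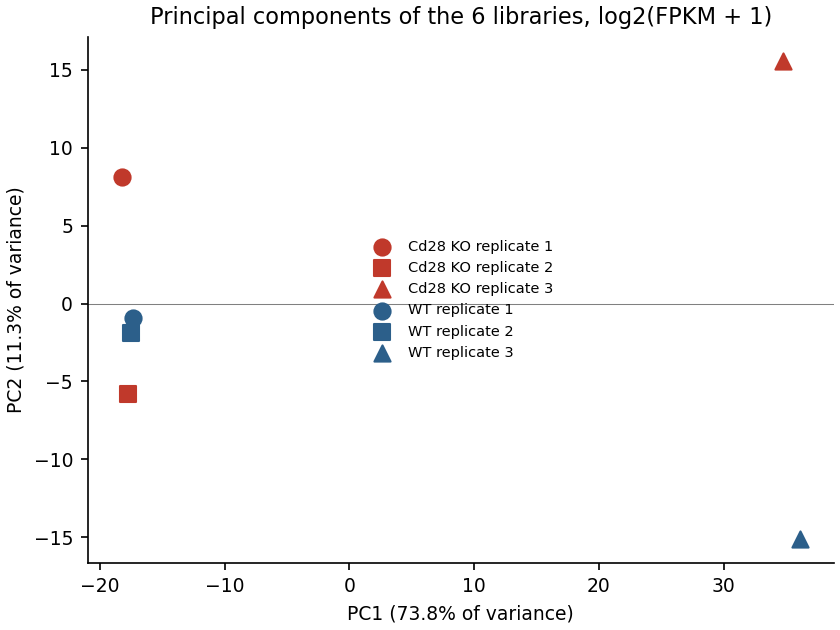
Principal components 1 and 2 of log2(FPKM + 1) over the tested genes, with 1 point per library, colour for genotype and shape for replicate number. Both replicate 3 libraries lie above 34 on component 1, and the other 4 lie below -17.

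The strongest difference in Cd28 KO macrophages was in Ctse, which encodes the aspartic protease cathepsin E. Ctse (Entrez 13034, chromosome 1, 131638314 to 131675507) rose 30.4-fold by the ratio of mean FPKM, from 4.18 ± 1.17 FPKM in WT to 127 ± 17.5 in Cd28 KO (SD, n = 3 each). Snx8 (Entrez 231834, chromosome 5, 140340293 to 140389308), a sorting nexin of endosomes, rose 4.59-fold, from 22.3 ± 1.06 to 102 ± 3.41 FPKM. Their log2 fold changes were 4.64 ± 0.19 and 2.15 ± 0.09 (SE), both at a limma adjusted p of 0.000294. These were the 2 genes called higher, both more than 2-fold, and 0 genes were called lower by limma. At an unadjusted p below 0.05, limma listed 253 of the 10172 genes. With the replicate number as a block, limma called 14 genes higher and 4 lower, 11 of them at least 2-fold, including Ctse and Snx8. A batch term for replicate 3, added after seeing the data, gave 20 higher and 8 lower, and replicates 1 and 2 alone gave 40 higher and 31 lower.

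Other genes higher in every Cd28 KO library than in any WT library did not pass the test without a block and did pass with it. Il1f9, a cytokine of the interleukin-1 family, stood at 8.31 ± 2.42 FPKM in Cd28 KO and 1.64 ± 0.393 in WT, with limma adjusted p = 0.16 without and 0.0046 with the block. B3gnt7, a glycosyltransferase, stood at 2.70 ± 0.188 against 0.373 ± 0.278 FPKM, with limma adjusted p = 0.16 and 0.0073. Steap3, a metalloreductase that acts on iron, stood at 78.7 ± 8.26 against 43.5 ± 1.80 FPKM, with limma adjusted p = 0.16 and 0.0075. Further genes called higher with the block, chosen after their values were seen, were Ugt1a6b, C130026I21Rik, Dynlt1b, Dynlt1c, Rab4a, Wdfy1, Ly6a, Hpgd and Isg15. Rab4a, a small GTPase of recycling endosomes, stood at 10.9 to 13.7 FPKM against 4.14 to 5.28. Hpgd, which breaks down prostaglandins, stood at 158 ± 38.6 against 100.3 ± 23.4 FPKM.

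Ugt1a6b, Dynlt1b, Dynlt1c and C130026I21Rik belong to families of similar copies, so their own values are uncertain. Ugt1a6b stood at 25.2 ± 8.92 against 1.69 ± 1.62 FPKM, and the sum over 3 listed Ugt1a genes was 102 to 121 FPKM in Cd28 KO and 47.8 to 65.3 in WT. Dynlt1b stood at 94.6 ± 13.9 against 38.6 ± 6.50 FPKM, and the sum over 4 listed Dynlt1 genes was 193 to 257 FPKM in Cd28 KO and 116 to 148 in WT.

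No gene was called lower without the block, so the rule named the lower genes of smallest p whose groups did not overlap. All of these lay on chromosome 1, but they were not the genes with the largest decreases. Itgax, on chromosome 7 and also without overlap, had a log2 difference of -0.78, against -0.58 for Mcm6. Nck2, an adaptor protein, stood at 2.11 ± 0.111 FPKM in Cd28 KO against 5.45 ± 0.842 in WT (limma adjusted p = 0.26, and 0.019 with the block). Stk11ip stood at 10.9 ± 0.837 against 21.5 ± 3.09 FPKM (limma adjusted p = 0.26, and 0.014 with the block). Acadl, an acyl-CoA dehydrogenase of fatty acid oxidation, stood at 26.8 ± 0.866 against 46.0 ± 5.10 FPKM (limma adjusted p = 0.26, and 0.029 with the block). Mcm6 stood at 36.1 ± 1.10 against 54.6 ± 2.36 FPKM and Ramp1 at 2.59 ± 0.340 against 5.17 ± 0.770, neither past the threshold in either fit. Rab7b, chosen after its values were seen, stood at 40.9 ± 16.7 against 116 ± 41.2 FPKM, with a limma adjusted p of 0.00011 with the block.

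**Figure D2:**
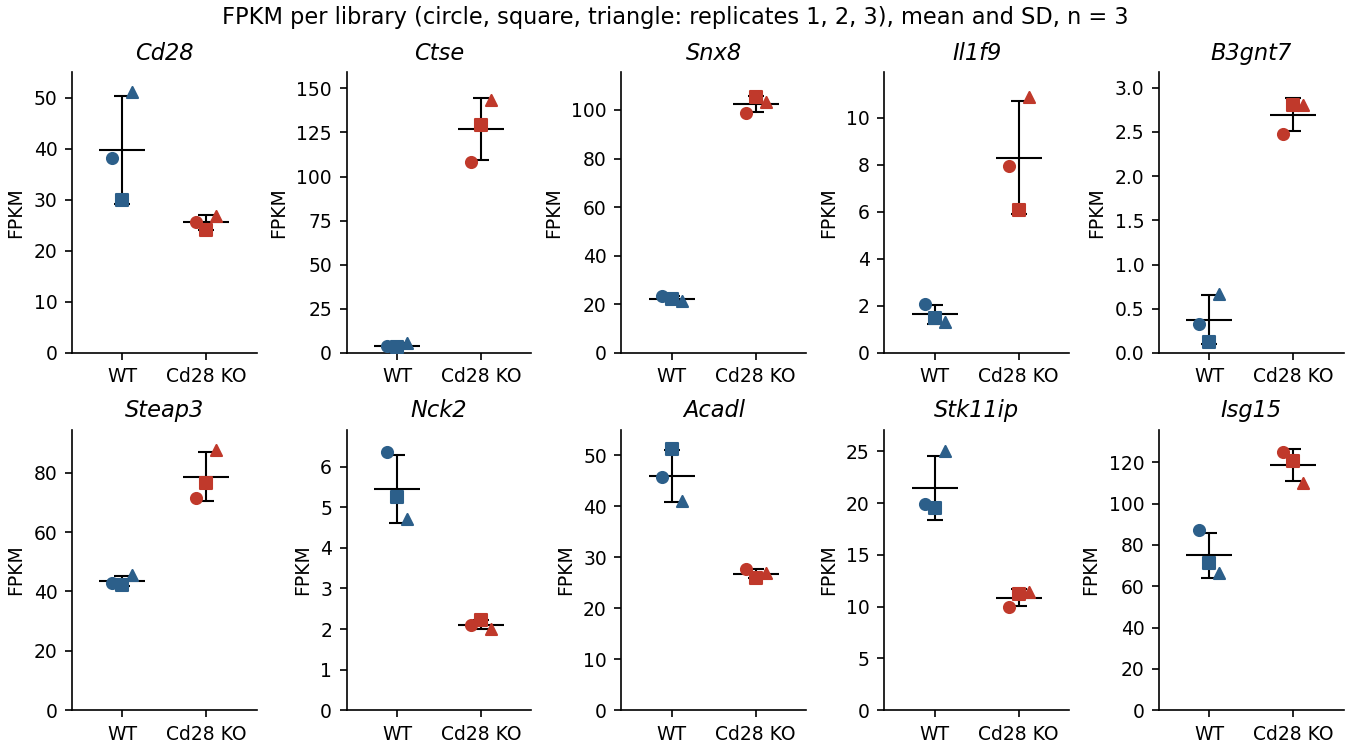
FPKM of 10 genes in each library, with 1 panel per gene and linear axes from 0, shapes for replicates, and the mean with SD over n = 3. Ctse lies at 108 to 143 FPKM in Cd28 KO and at 3.35 to 5.52 in WT.

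Positions of the called genes were compared with that of Cd28, since a targeted allele can carry neighbouring sequence with it. Without a block, 0 of 67 tested genes within 10 Mb of Cd28 were called by limma, and with the block 1 was (Fisher's exact p = 0.112). Within 20 Mb, 0 of 123 were called without a block and 4 with it (odds ratio 24.1, Fisher's exact p = 5.5e-05), and within 5 Mb 0 of 39 in both fits. Over the whole chromosome, 10 of the 18 genes called with the block lay on chromosome 1, which held 578 of the 10172 tested genes (odds ratio 21.1, Fisher's exact p = 9.4e-09, computed after seeing the data). These 10 lay between 43445483 and 131715443. With the batch term for replicate 3, 14 of 28 called genes were on chromosome 1. In replicates 1 and 2 alone it was 18 of 71 (25.4%, odds ratio 5.78, Fisher's exact p = 5.4e-08). With array weights, which rest mostly on replicate 1 of each group, it was 83 of 928. Without a block it was 1 of 2 (Fisher's exact p = 0.11).

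**Figure D3:**
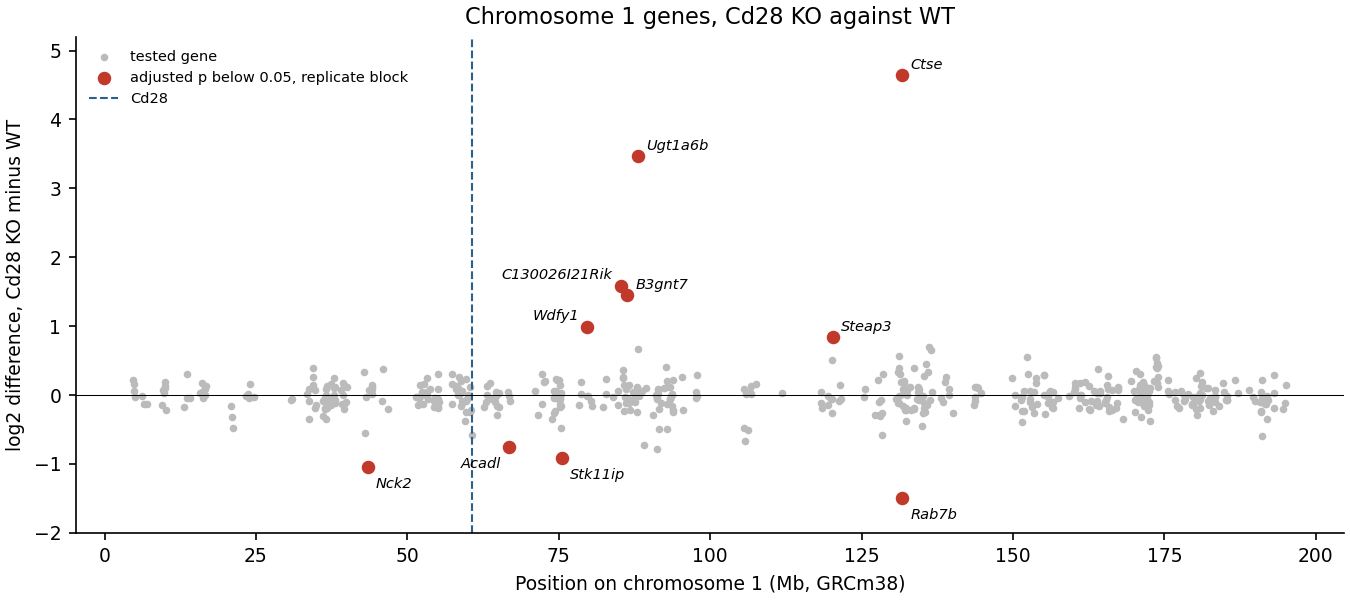
The log2 difference of each tested gene on chromosome 1, Cd28 KO minus WT, against its position in Mb, with the 10 genes called under the replicate block in red and Cd28 as a dashed line. Called genes lie on both sides of 0, from Nck2 to Rab7b.

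Interferon-stimulated genes, the antiviral genes that interferons switch on, were higher in Cd28 KO as a group. Of the 38 tested members 37 had a positive difference, with a median log2 of 0.32, and 16 (42.1%) were higher in every Cd28 KO library than in any WT library. Among all 10172 tested genes, 3.84% were higher and 2.87% lower without overlap. Exchangeable libraries would give 5% in each direction and 10% in all, but the replicate 3 libraries of both groups stood apart. None of the 38 members was called over all genes by limma, and 11 passed when adjusted over the list alone. The 11 became 22 with the block, 3 on the TPM scale, 5 with quantile normalization, 1 without WT replicate 1, and 0 without Cd28 KO replicate 1, Cd28 KO replicate 2 or WT replicate 2. With the block, limma called 1 over all genes, Isg15, and 0 when median centring, quantile normalization, no filter or leaving out chromosome 1 was added. More were called with the batch term (3), in replicates 1 and 2 alone (8) and with array weights (25), which rest mostly on replicate 1 of each group. Isg15 stood at 119 ± 7.71 FPKM in Cd28 KO against 75.0 ± 10.9 in WT, Zbp1 at 76.7 ± 9.01 against 49.4 ± 3.57, Xaf1 at 22.8 ± 0.189 against 15.0 ± 1.17 and Ifi44 at 22.5 ± 3.51 against 14.5 ± 0.680 (SD, n = 3 each). The list passed limma's camera at an adjusted p of 2.6e-27 with the preset correlation, and did not with an estimated correlation (adjusted p = 0.081) or with fry (adjusted p = 0.11). The 6 libraries were also split into 3 and 3 in ways that mix the genotypes. Camera with the preset correlation then gave this list unadjusted p values from 1.0e-10 to 0.50, against 7.8e-29 for the real split. Small p values at the preset correlation thus also arose without the genotype grouping. With an estimated correlation in each alternative, added after seeing the data, the adjusted p ranged from 0.042, with median centring, to 0.82.

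Genes of lipid handling, among them targets of the sterol receptor LXR, were lower as a group. All 22 tested members had a negative difference, with a median log2 of -0.21. Acadl was the 1 member past the threshold when adjusted over the list alone, 2 were with the block, and 5 members were lower in every Cd28 KO library. Acadl lies on chromosome 1 between the outermost genes called with the block. Over the 21 members on other chromosomes the median was -0.19. Abcg1, a cholesterol exporter, stood at 54.3 ± 4.49 FPKM against 63.4 ± 2.44 in WT, Scd1 at 16.0 ± 2.47 against 21.1 ± 2.73, and Lpl at 937 ± 100 against 1161 ± 188. The list passed camera at a limma adjusted p of 5.0e-10, and had an adjusted p of 0.081 with an estimated correlation.

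A group of 4 tested monocyte markers was higher, with a median log2 of 0.65. Ly6a stood at 95.1 ± 14.5 FPKM against 43.4 ± 15.9 in WT and was called with the block (limma adjusted p = 0.042), while Plac8 stood at 7.66 ± 1.61 against 3.59 ± 1.97. S100a4 and Ccr2 had log2 differences of 0.32 and 0.26. Camera gave the list a limma adjusted p of 6.2e-06, and 0.081 with an estimated correlation. The list has 11 markers, of which the filter kept these 4, and it did not pass without the filter, with or without the block, where the median over all 11 was 0.06.

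Ribosomal protein genes and genes of oxidative phosphorylation were also higher, with larger medians in replicate 3, a difference that was not tested. All 40 ribosomal members were positive, with a median log2 of 0.19, which was 0.08 in replicates 1 and 2 and 0.42 in replicate 3. It was 0.09 with quantile normalization, where 8 members were negative, 0.13 on the TPM scale, where 3 were, and 0.31 without Cd28 KO replicate 2. For oxidative phosphorylation, 28 of 35 members were positive and the median was 0.13, with 0.00 in replicates 1 and 2 and 0.32 in replicate 3. It was 0.07 on the TPM scale, where 12 members were negative, 0.08 with array weights or without Cd28 KO replicate 1, 0.20 without Cd28 KO replicate 2 and 0.05 without WT replicate 3. MHC class I genes had a median of 0.14, with 12 of 15 members positive, among them Psmb9 at 63.8 ± 3.78 FPKM against 50.4 ± 6.39. This median was 0.08 on the TPM scale, where 4 members were negative, 0.05 with array weights, and 0.09, 0.08 and 0.09 without Cd28 KO replicate 2, Cd28 KO replicate 3 and WT replicate 3, respectively. Camera's adjusted p values from limma were 3.2e-16, 3.2e-05 and 0.0005 for these lists, and 0.55, 0.81 and 0.38 with an estimated correlation. In replicates 1 and 2 alone they were 0.16, 0.78 and 0.26. With array weights and without Cd28 KO replicate 3, oxidative phosphorylation (0.16 and 0.35) and MHC class I (0.42 and 0.19) did not pass, nor did oxidative phosphorylation without WT replicate 3 (0.10).

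Markers of osteoclasts and fused macrophages were lower, with a median log2 of -0.36 over 9 members, which was -0.51 in replicates 1 and 2 and 0.02 in replicate 3. It was -0.20 without the genes of chromosome 1, -0.22 without Cd28 KO replicate 2 or without WT replicate 2, and -0.10 over 12 members without the filter, and the list passed in each. Tnfrsf11a, which lies on chromosome 1 between the outermost genes called with the block and encodes the receptor for the osteoclast factor RANKL, stood at 8.78 ± 2.66 FPKM against 14.2 ± 1.70. Lysosomal genes had a median of -0.03, with 22 of 28 members negative and Gpnmb at 2118 ± 240 FPKM against 2682 ± 184. This median was -0.12 with quantile normalization, -0.10 on the TPM scale, -0.07 with array weights or without Cd28 KO replicate 3, and -0.06 without WT replicate 1, without WT replicate 3 or in replicates 1 and 2. In replicate 3 it was 0.03. M-CSF type macrophage genes had a median of 0.11, with Fcrls at 175 ± 11.7 against 139 ± 21.9. Their median was 0.05 on the TPM scale, 0.07 with array weights or without Cd28 KO replicate 2, and 0.18 without Cd28 KO replicate 3. It was 0.26 in replicates 1 and 2 and -0.03 in replicate 3. Camera's limma adjusted p values were 0.0015, 0.023 and 0.045 for these lists, and 0.24, 0.24 and 0.38 with an estimated correlation. With the replicate block, the lysosomal and M-CSF lists no longer passed (limma adjusted p = 0.15 and 0.20), and neither passed without the filter. The lysosomal list also did not pass without Cd28 KO replicate 1 (0.16), Cd28 KO replicate 2 (0.17) or WT replicate 3 (0.0995). It did pass camera with quantile normalization added to the block (limma adjusted p = 0.00075, and 0.65 with an estimated correlation). The M-CSF list did not pass on the TPM scale (0.054), with a minimum mean of 5 FPKM (0.084), quantile normalization (0.26), array weights (0.41) or chromosome 1 left out (0.12), in replicates 1 and 2 (0.15), or without Cd28 KO replicate 2 (0.16), Cd28 KO replicate 3 (0.23) or WT replicate 2 (0.35). Chemokines did not pass without a block (0.094) and passed as higher with it (4.4e-05), with the batch term (4.9e-05), on the TPM scale (0.025), in replicates 1 and 2 (0.011), and without Cd28 KO replicate 1 (0.0055), Cd28 KO replicate 2 (0.0035) or WT replicate 3 (0.0016), while without Cd28 KO replicate 3 their median was -0.06. Cholesterol synthesis passed as lower with the block (0.021), the batch term (0.021), a minimum mean of 5 FPKM (0.043) or array weights (0.0044), in replicates 1 and 2 (0.0037), and without Cd28 KO replicate 1 (0.012), Cd28 KO replicate 2 (0.039) or WT replicate 3 (8.3e-05), while without Cd28 KO replicate 3 or WT replicate 1 its median was 0.04 and 0.02. Neither passed with an estimated correlation in any of these settings. Altogether 9 of 33 lists passed camera, and 14 did without Cd28 KO replicate 3 or without WT replicate 3.

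**Figure D4:**
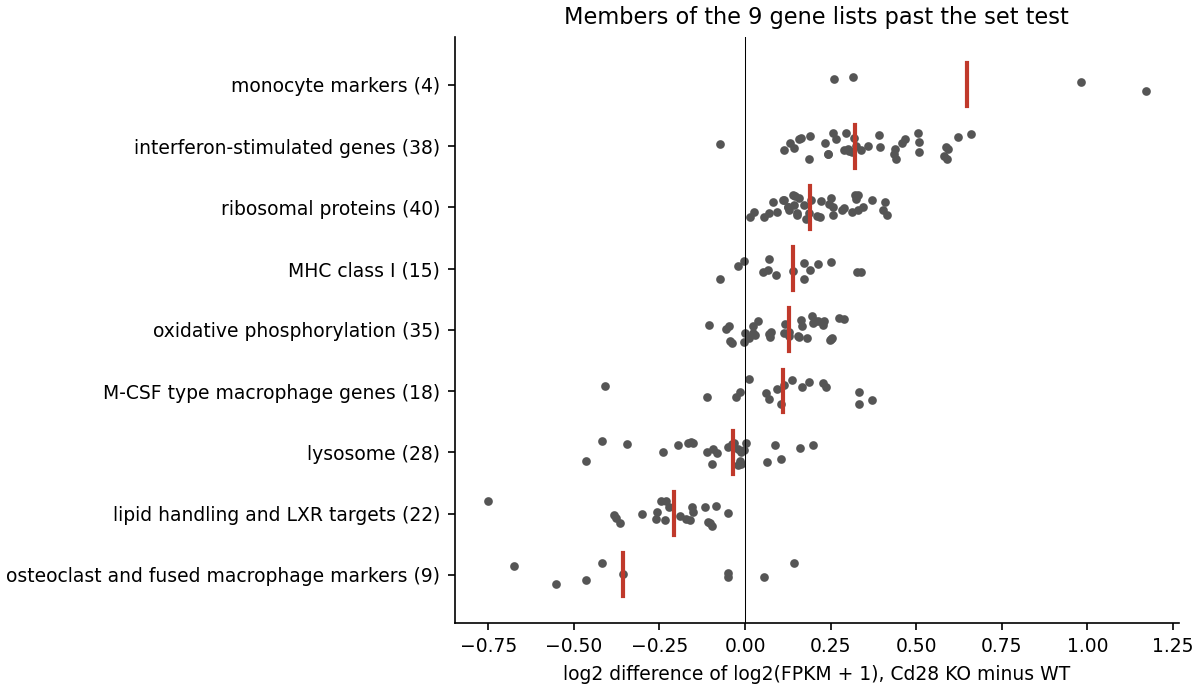
The log2 difference, Cd28 KO minus WT, of each tested member of the 9 lists past camera, with 1 point per gene, a red line at the median and the number of members in brackets. The median of interferon-stimulated genes lies at 0.32 and that of lipid handling genes at -0.21.

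The other 24 tested lists did not pass, with limma adjusted p values from 0.083 for cholesterol synthesis to 0.92 for alternative activation. MHC class II genes had a median log2 of -0.04, which was -0.24 in replicates 1 and 2 and 0.17 in replicate 3. They passed camera as lower in replicates 1 and 2 alone (limma adjusted p = 0.0042), with quantile normalization (0.022), with array weights (0.012), without Cd28 KO replicate 3 (0.027), without WT replicate 3 (0.042) and with quantile normalization and the block (0.039). With an estimated correlation the adjusted p was 0.88 over all libraries and 0.59 to 0.84 in those settings. Glycolysis and hypoxia genes had 20 of 24 members negative, with a median of -0.04, which was -0.11 in replicates 1 and 2 and 0.06 in replicate 3. They passed camera as lower in replicates 1 and 2 alone (limma adjusted p = 0.0077), with quantile normalization (0.027, and 0.016 with the block), with array weights (0.0044) and without Cd28 KO replicate 3 (0.0012), where the adjusted p with an estimated correlation was 0.45 to 0.84. Cd74, the invariant chain, stood at 1674, 1715 and 1733 FPKM in Cd28 KO and 2005, 2633 and 1539 in WT. Costimulatory and coinhibitory ligands, which include those that bind Cd28 family receptors, had a median of 0.06, inflammatory mediators -0.06, chemokines 0.25, immediate early genes -0.05, and cholesterol synthesis -0.07. GM-CSF type genes (0.06), alternative activation (0.00), phagocytic and scavenger receptors (0.04), innate sensors (0.04), complement (0.06) and macrophage identity (0.02) had medians near 0. So did cell cycle (0.03), unfolded protein response (0.05), amino acid stress (0.01), heat shock (-0.06), oxidative stress and metals (-0.02), matrix and proteases (-0.09), p53 targets (0.10) and genes around Cd28 (-0.06). Neutrophil markers (-0.09), dendritic cell markers (0.06) and sex-linked genes (-0.14) completed them. Immediate early genes, inflammatory mediators and the amino acid stress list passed camera as lower without Cd28 KO replicate 3 (limma adjusted p = 2.5e-05, 0.00042 and 0.027) and as higher without WT replicate 3 (0.049, 0.020 and 0.0015). Matrix and proteases (0.00043) and oxidative stress and metals (0.0084) passed lower without Cd28 KO replicate 3, inflammatory mediators lower without WT replicate 2 (0.042), and costimulatory and coinhibitory ligands higher without WT replicate 3 (0.018). Cell cycle (0.0078) and amino acid stress (0.012) passed higher without Cd28 KO replicate 1, and innate sensors higher without Cd28 KO replicate 3 (0.0498) and in replicates 1 and 2 (0.033). None of these passed with an estimated correlation in the same settings (adjusted p = 0.42 to 0.94).

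Most markers of other cells fell below the filter in both groups. Of T and NK cell, B cell, stromal and erythroid markers 1 gene each was tested, and of mast cell, basophil and eosinophil markers 2, so these lists had no set test with the filter. Without the filter, the mast cell, basophil and eosinophil list passed camera as lower, with 8 of 11 members negative and a median log2 of -0.15 (limma adjusted p = 0.0037, and 0.0068 with the block), and did not with an estimated correlation (adjusted p = 0.49, and 0.82 with the block). Its members below the filter did not exceed 1.32 FPKM in any library. Cd3e and Col1a1 did not exceed 0.09 FPKM in any library. Among those tested, the B cell list's Blnk stood at 72.8 to 87.5 FPKM, the dendritic list's Bst2, also an interferon-stimulated gene here, at 289 to 429, the stromal and endothelial list's Kdr at 4.45 to 17.4 and Cd4 at 2.95 to 6.42, while the macrophage gene Lyz2 reached 9652 to 12716 FPKM. Kit did not exceed 1.74 FPKM in Cd28 KO and stood at 2.80, 3.12 and 3.88 in WT, not past the threshold over all genes (limma adjusted p = 1.00), and was the 1 of 2 tested members of that list past it when adjusted over the list alone. Nnt, a gene whose copy differs between mouse substrains, stood at 8.92, 8.49 and 6.57 FPKM in Cd28 KO and 8.02, 8.42 and 6.43 in WT.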

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

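The test of whether the genotype difference itself differed between replicate 3 and replicates 1 and 2 was chosen after the libraries were seen to separate that way. In limma, 7 of 10172 genes passed at an adjusted p below 0.05, against 1918 at an unadjusted p below 0.05. Replicate 3 is 1 library against 1, so the fit assumes that these vary like the others. The difference in log2 fold change, replicate 3 minus replicates 1 and 2, was 2.81 for Erdr1 (-1.09 in replicates 1 and 2, 1.72 in replicate 3), 1.83 for Cpne8, -2.73 for H3c15, -2.51 for Cd300ld4, -1.85 for Evi2, -1.78 for Gatad2b and -1.71 for 9930111J21Rik2. No explanation was tested for these genes.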

How the results depend on the processing

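Ctse and Snx8 were called under every setting that tested them, with log2 fold changes of 4.53 to 4.92 and 2.06 to 2.19, respectively. Of 107 named genes 7, none of them called in either fit, changed sign in 22 values: Cd4, Blnk, Kdm5d, Ddx3y, Eif2s3y, Nnt and Kdr. Of the 2482 gene values under alternatives, 2306 stayed on their side of the threshold, 176 newly passed it and 0 fell below it. Without a block only Ctse and Snx8 were called, so only these 2 genes could fall below it. The difference in Cd28 kept its sign, from -8.56 FPKM without WT replicate 3 to -19.1 without WT replicate 2, and -9.22 in replicates 1 and 2. The smallest exact p these designs allow is 0.1 or above, so its p says nothing on stability. The paired exact sign-flip p, with the block, was 0.25, the smallest possible. The alternatives that leave out chromosome 1, use a batch term or keep replicates 1 and 2 alone, and those that combine the block with other settings, were added after seeing the data. Unless said otherwise the cause was not tested.

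Counts are given as higher, lower and at least 2-fold, then genes near Cd28, against 2, 0, 2 and 0. The replicate block gave 14, 4, 11 and 1. The batch term gave 20, 8, 11 and 1. Replicates 1 and 2 gave 40, 31, 23 and 1. Array weights gave 604, 324, 19 and 5. The weights were 5.97 for Cd28 KO replicate 1 and 4.81 for WT replicate 1. They were 0.67 for Cd28 KO replicate 2, 1.63 for WT replicate 2 and 0.18 for both replicate 3 libraries. The fit with array weights therefore rests mostly on replicate 1 of each group. No filter gave 3 lower and 1 near. The block with median centring gave 10, 3 and 11, with quantile normalization 12, 4, 10 and 1, with a pseudocount of 0.1 FPKM 14, 4, 12 and 1, and with no filter 2, 1, 3 and 0, so that 3 of the 18 genes called with the block remained. Without chromosome 1 the counts fell to 1 higher and 1 at least 2-fold, to 4 and 4 with the block and to 9 and 5 with the batch term. In the full fits 8 and 14 calls lay on other chromosomes, so calls elsewhere were lost too. The Benjamini-Hochberg adjustment ranks all genes together. Taking out small p values on chromosome 1 can therefore raise the adjusted p of other genes without a change in those genes. Whether this accounts for the whole loss was not tested.

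Lists past the set test numbered 9, and 0 with an estimated correlation or fry, with or without the block. Median centring with an estimated correlation, also added after seeing the data, gave 1, the interferon-stimulated genes. Leaving out 1 library gave 9 to 14 lists, 2 genes higher and 0 lower. Adjusted over each list alone, members past the threshold rose with the block from 11 to 22 for interferon-stimulated genes, 0 to 4 for chemokines, 1 to 2 for lipid handling, 0 to 2 for GM-CSF type genes, and 0 to 1 for M-CSF type, alternative activation, complement, amino acid stress, neutrophil and osteoclast genes. Apart from these and the values in the report, the block changed no call of a gene, list or window.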

Other observations

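The tests of scaling, of chromosome 1 members, of sex and neutrophils, of the direction of the chromosome 1 genes, the counts of genes and lists over other splits of the libraries, and all comparisons with the splits that part all pairs were chosen only after the results were seen.

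Replicate 3 of both genotypes held a different expression state. Adjusted for genotype, limma called 1110 genes higher and 2412 lower in replicate 3, with 282 and 201 at least 2-fold. Of 23 immediate early genes 17 were called higher and 3 lower, with a median log2 of 1.08, and of 16 inflammatory mediators 13 higher and 1 lower, with a median of 1.00. Cxcl2 stood at 109 and 116 FPKM in the replicate 3 libraries of Cd28 KO and WT and at 1.74 to 3.33 in the other 4, Tnf at 131 and 139 against 20.8 to 25.4, and Cd86 at 26.1 and 26.0 against 2.37 to 3.77. Of 23 cholesterol synthesis genes 12 were called lower and 0 higher, among them Hmgcs1 at 12.4 and 12.5 against 46.5 to 55.8 FPKM. These lists had limma adjusted p values of 1.5e-13, 1.6e-11 and 0.00031 with the preset correlation, and 0.12, 0.12 and 0.18 with an estimated correlation.

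The first pattern weighed is that state of replicate 3. Y-linked genes were listed in these libraries, but 3437 of the genes that differed lay on autosomes. Genes of the sex chromosomes therefore do not make up the difference by themselves. The share on X or Y was 2.36%, and 2.27% of the differing genes lay on X, against 3.12% of the tested genes. With 317 tested genes on X, a low share was bound to come out, so it does not decide whether sex plays a part. Neutrophils are argued against by S100a8 and S100a9, which did not exceed 4.44 FPKM there. An effect of sex on other genes, a batch and an activation of these cultures cannot be told apart. No label used here gives sex or batch, and both replicate 3 libraries stood apart together.

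For the second pattern, the crowding of called genes on chromosome 1, a candidate explanation is that alleles of another strain came along with the Cd28 target. A test fixed before its result was seen used the 222 uncalled genes between the outermost calls. Of these, 15.8% had an unadjusted p below 0.05 in the limma fit with the block, against 7.43% on other chromosomes (odds ratio 2.33, 95% interval 1.56 to 3.39). The higher share goes with that hypothesis, though Cd28 itself, at an unadjusted limma p of 0.00087, was among the 222 genes. Among all tested genes, called ones included, the share was 9.09% of 22 genes at 60 to 70 Mb, which holds Cd28. It was 28.6% of 14 genes at 40 to 50 Mb, 38.9% of 18 at 120 to 130 Mb and 24.1% of 54 at 130 to 140 Mb. These bins hold too few genes to tell where the share is highest, and they do not count for or against the hypothesis. A fall with distance from Cd28 was not tested, and the calls themselves set the ends of the interval. Poorer alignment of variant reads would lower genes in Cd28 KO, and 4 called genes there without near-identical copies were higher. For the lower genes it stays open, since the median of the interval differed from other chromosomes by -0.0066 (95% bootstrap interval -0.03 to 0.01). Strain alleles and the Cd28 genotype are confounded in this design, and Snx8 and other called genes lie elsewhere.

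The third pattern is the higher level of interferon-stimulated genes. Scaling is argued against by a median log2 of at least 0.307 with median centring and quantile normalization. The TPM scale, which that test left out, gave 0.273. The pattern was not confined to members on chromosome 1, since 34 of the 38 lie elsewhere and had a median of 0.33. Leaving out so few members could hardly have moved the median. Effects of chromosome 1 alleles on members elsewhere were not tested. Of the 4 splits that part all pairs 1, the real one, gave an absolute median as large as its 0.32, and the highest other was 0.174. Over all 10 splits it was 1 too, and the highest other, 0.302, came from a split that parts 1 pair. These splits are too few for a share under 0.05. An effect of the Cd28 genotype, of strain background and of housing stay open as untested.

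For the counts of genes, 1 of the 10 splits, the real one, reached 2 called genes and 2 genes at least 2-fold, and the highest other was 0 for both. The same held among the 4 splits that part all pairs. For the lists, 5 of the 10 splits reached 9 and the highest other reached 12, and among the 4 it was 2, with a highest other of 10. With the replicate block, 1 of the 4 splits that part all pairs, the real one, reached 18 genes, and the highest other was 0. With 10 splits the share cannot go under 0.1, and with 4 not under 0.25.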
